A study of Mus musculus with 6 samples.

How the data were processed

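Bulk ATAC-seq libraries from 50000 cells each were made from mouse small intestinal organoids and sequenced at a read length of 38 bp, per the labels' protocols. RANKL was given at 100 ng/ml for 6 days, after 3 days of 3 µM CHIR99021 with 1.5 mM valproic acid and a day in ENR medium, per the labels' protocols. Samples were grouped by the treatment in their labels into RANKL and control (n = 3 each).

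The authors deposited raw read counts in 55056 windows of 200 bp, whose centres lay at least 4003 bp apart, and these whole-number counts were the main measurement. The authors also deposited a score per 2-kb window around 55050 of the same centres, in which each library has mean 0 and SD 1. From the values, this score is the natural log of a count plus 1, centred and divided by its SD within each library: the 2-kb counts recovered from it lay within 0.013 of a whole number in every library, and no 200-bp count exceeded the 2-kb count around it. The submitters' processing notes name fastp 0.20.1, BWA 0.7.17, Picard, MACS2 2.2.7 and DESeq2 1.34.0 and the builds mm10 and GRCm38, without a role for each. How windows were chosen, how reads were counted, and whether read ends were shifted for the Tn5 cut or duplicates and mitochondrial reads removed are not given in the sources used here. Windows of fixed width placed at least 4003 bp apart can hold part of a broad region and leave out its neighbours, and counts in 200 bp are low: 3.93% to 18.0% of windows had a count of 0 in a library.

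Totals of 322173 to 976881 counts per library set the precision, 3 counts being worth 3.07 to 9.31 CPM. Reads carry no molecular identifiers as far as the labels say. The binomial intervals for shares of reads treat the reads of a library as independent, so they cover counting error at most and no differences between libraries. Duplicate reads counted as separate would make them too narrow. The central 200 bp held 39.9% to 41.0% of the 2-kb reads in control libraries and 33.9% to 36.5% in RANKL libraries.

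Window start positions were taken as counted from 0 and are printed counted from 1. Gene positions came from a RefSeq table of GRCm38.p6 with 21896 protein-coding genes and no strand, so transcription starts were unknown. The test fixed in advance used the nearest transcription start; in its place each window was assigned to the nearest end (start or end) of a protein-coding gene within 50 kb, which took in 38490 windows (69.9%). Windows had first been assigned to the nearest gene body, and this was replaced after first results had been seen; both versions are compared with the other alternatives. As a check of the build, 18.7% of windows lay within 1 kb of a gene end, against 3.76% after shifting them by 1 Mb. "Inside" and "outside" a gene refer to its body, and exons, introns and UTRs were not told apart.

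Windows and gene sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05; CPM values use edgeR's library sizes. TMM factors were 0.99 to 1.01 for windows. SE is the absolute log2 fold change divided by the root of the F statistic. The 21 gene lists, fixed before the data were examined, with 518 symbols matched, covered M cells, the NF-kB pathway, antigen presentation, crypt stem cells, goblet, Paneth, tuft and enteroendocrine cells, enterocytes, villus tip, villus bottom, fatty acid oxidation and PPAR targets, intestinal transcription factors, fetal or regenerative epithelium, cell cycle, endocytosis and lysosome, housekeeping genes, and immune, mesenchymal, endothelial and neural cells. They were tested with camera in limma 3.58.1 (correlation preset at 0.01, adjusted over the 21 lists) and with fry, whose p tests whether a list's genes move on balance in a single direction. A window was distal when over 1 kb from any gene end.

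Genes were named by a rule fixed before the data were examined. It took 14 genes of interest; the 10 largest rises and 10 largest falls among called genes with at least 2 windows, mean log2 CPM at or above the median and all RANKL libraries on the same side of all controls, leaving out predicted gene symbols; up to 4 members of each list with the smallest adjusted p; and the 5 largest rises and falls among well covered called windows. A gene that the rule takes is not reported here. Genes named outside it are marked as chosen after their values were seen.

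On simulated counts with the real means, dispersions and library sizes, the windows test (21618 windows) recovered 85 of 100 windows changed 4-fold and 46 of 100 changed 2-fold and called 8 of the 19244 unchanged windows that passed the filter, and the gene test (12465 genes) recovered 98 of 100 and 63 of 100 and called 7 of 11870 unchanged genes. A simulated list raised by 1.5-fold was called in both and none of 20 unchanged lists was. The simulated features were drawn independently, whereas correlations estimated for the real lists reached 0.111. The simulation therefore does not show how often correlated unchanged lists would be called.

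The replicate numbers pair the groups by the labels, which give each number as an experiment. In the data, the correlation across windows of deviations from the group mean was -0.03, 0.01 and -0.01 for libraries of the same number and -0.03 to 0.04 for other pairs. The fit with the number as a block was an alternative.

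Alternatives were DESeq2 1.42.0 and its size factors, total counts, other filters, limma-voom, loess offsets, stricter thresholds, other distances, the replicate block, leaving out each library, and, chosen after seeing the data, 2-kb counts, the deposited scores, thinning to the same depth, leaving out windows held mainly by a single library, and the nearest gene body. The planned motif tests and corrections for GC content need a genome sequence and were not run. Figures were drawn with matplotlib 3.10.9.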

Results

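Chromatin accessibility was profiled by bulk ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, in mouse small intestinal organoids, self-organising epithelial cultures grown in a basement membrane gel. The 6 libraries formed 2 groups of 3: organoids treated for 6 days with RANKL, the TNF family cytokine that drives differentiation of microfold (M) cells, and control organoids in ENR medium, which contains EGF, Noggin and R-spondin 1. The series title names the transcription factor ONECUT2 in RANKL-dependent differentiation of enterocytes and M cells, and the only comparison the labels give is RANKL against control. The replicates were independent differentiation experiments per the labels. The treated cultures had been exposed to CHIR99021, a GSK3 inhibitor, and valproic acid before RANKL, and the labels do not state whether the controls had too. The submitters' names for the control libraries begin with CVENR, which the labels do not explain. A difference between the groups can therefore hold both treatments. The counts covered 55056 windows of 200 bp on the GRCm38 (mm10) genome. Their total was 920681, 976881 and 455083 in control replicates 1, 2 and 3, and 322173, 466521 and 828445 in RANKL replicates 1, 2 and 3, with a median of 3 to 11 counts per window.

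RANKL-treated organoids had many windows of higher and many of lower accessibility. Of 21618 windows deep enough to test, 2166 were higher and 2169 lower at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, n = 3 per group), and 6754 had an unadjusted p under 0.05. The median change was 2.45-fold among the higher windows and 2.39-fold among the lower ones. In 33.4% of all tested windows, called or not, all 3 RANKL libraries lay on the same side of all 3 controls, against 10% by chance. Between libraries, the Pearson correlation of log2 CPM across windows, which are not independent replicates, was 0.82 to 0.87 among controls, 0.69 to 0.77 among RANKL libraries and 0.44 to 0.54 between the groups. Without RANKL replicate 3 the number of higher windows was 1337, and DESeq2 called 1264 higher and 1039 lower.

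The largest changes among well covered windows lay both inside and outside protein-coding genes, which are named here only as the nearest ones. A window at chromosome 12, 21520476 to 21520675, 103139 bp from the nearest end of Ywhaq, rose from 2.30 ± 0.76 to 110.8 ± 32.3 CPM (SD, n = 3 per group), a log2 fold change of 5.44 ± 0.45 (SE) with an edgeR adjusted p of 2.562e-29. Windows inside Ttc6, inside Cd200r2 and 10684 bp outside Trabd2b rose by log2 fold changes of 4.00, 3.93 and 3.77, and a window whose nearest protein-coding gene was Diaph3, 424632 bp away, rose by 4.93. The largest fall was at chromosome 17, 15939191 to 15939390, 108044 bp from Rgmb, where accessibility went from 75.7 ± 6.0 to 5.33 ± 2.91 CPM (SD, n = 3 per group), a log2 fold change of -3.84 ± 0.45 (SE). Windows 8342 bp outside Olfr948, 28972 bp outside Ambn and inside Col8a1 and Vapb had log2 fold changes of -3.44, -3.19, -3.12 and -3.11.

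Higher and lower windows differed in their place relative to genes. Windows more than 1 kb from any gene end, called distal here, made up 60.9% of the higher windows, 82.6% of the lower windows and 56.8% of the tested windows (two-sided Fisher's exact test of higher against lower, p = 3.122e-57, odds ratio 0.329, 95% interval 0.285 to 0.380). Windows are not independent samples, so this p and interval describe the windows of these 6 libraries. Without each library in turn the odds ratio was 0.341 to 0.604, the latter without control replicate 1. In counts of 2-kb windows around the same centres the direction was the opposite, with 88.9% of higher and 66.0% of lower windows distal. With loess offsets, which remove any trend with abundance, the 2-kb counts had 72.0% of higher and 78.2% of lower windows distal (odds ratio 0.716).

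Counts were summed over the windows whose nearest gene end belonged to a gene and lay within 50 kb. Of 12465 genes tested, 869 were higher and 1052 lower with RANKL (edgeR adjusted p at or under 0.05), and 3498 had an unadjusted p under 0.05. DESeq2 called 408 higher and 487 lower, and without RANKL replicate 3 the edgeR counts were 545 and 678. The nearest gene need not be the gene a window regulates, and gene names below mark places.

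The list of markers and regulators of M cells was called higher with RANKL. Of 23 tested members of this list 6 rose, 1 fell and 16 were not called with adjustment over all genes. The list was higher as a group (camera, preset correlation 0.01, adjusted p = 3.404e-06). The call was lost in camera with an estimated correlation (adjusted p = 0.1004). That estimate, 0.00196, was below the preset 0.01, so a larger correlation did not end the call. Adjusted over the list alone, 11 members were higher and 1 lower. H2-M2, a non-classical MHC class I gene at chromosome 17, 37480851 to 37483554, went from 2.75 ± 2.82 to 70.3 ± 6.8 CPM (SD, n = 3 per group), a log2 fold change of 4.32 ± 0.52 (SE) with an edgeR adjusted p of 1.07e-13. It had a single window, with 5.64, 2.62 and 0 CPM in control replicates 1, 2 and 3. Sox8, a transcription factor needed for M cell maturation (chromosome 17, 25565893 to 25570686), rose by a log2 fold change of 3.41 ± 0.71 (SE), from low counts: its window 28529 bp outside the gene held 1, 0 and 0 counts in the controls and 4, 13 and 11 with RANKL. Marcksl1 rose by 2.52 ± 0.34 and Msln, which encodes mesothelin, by 2.85 ± 0.49 (log2 fold change, SE). Msln had a single window, with 5.64 to 9.15 CPM in the controls. Within 1 kb of a gene end Marcksl1 had 1.39 (adjusted p = 0.05383). Tnfrsf11a, which encodes the RANKL receptor RANK and is in the NF-kB list too, rose by 0.49 ± 0.15 with an edgeR adjusted p of 0.01328, a call that ended in 6 alternative settings, among them leaving out control replicate 2 (adjusted p = 0.06751), control replicate 3 (0.09024) or RANKL replicate 3 (0.1129). Cyba also rose, and Atoh8, a transcription factor known to restrain M cell differentiation, was the member that fell, by 0.62 on the log2 scale (both chosen after their values were seen).

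Some M cell genes were too shallow to test, and others were not called in the sum over their windows. The single window at Spib, which encodes an Ets factor required for M cells, lay 49 bp outside the gene and held 1, 3 and 0 counts in the controls and 6, 6 and 22 with RANKL. At Gp2, the M cell receptor for FimH-bearing bacteria, the windows within 50 kb held at most 9 counts in any library. Tnfaip2 had a log2 fold change of 0.85 ± 0.34 (SE) with an edgeR adjusted p of 0.07081. Ccl20, a chemokine of the follicle-associated epithelium, had windows that moved apart: the window 159 bp inside a gene end had a log2 fold change of -0.94 ± 0.34 (SE, edgeR adjusted p = 0.03188) and that 16820 bp outside rose by 1.97 ± 0.40 (adjusted p = 2.8e-05), so that their sum was 0.06 ± 0.18 (adjusted p = 0.8714).

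**Figure D1:**
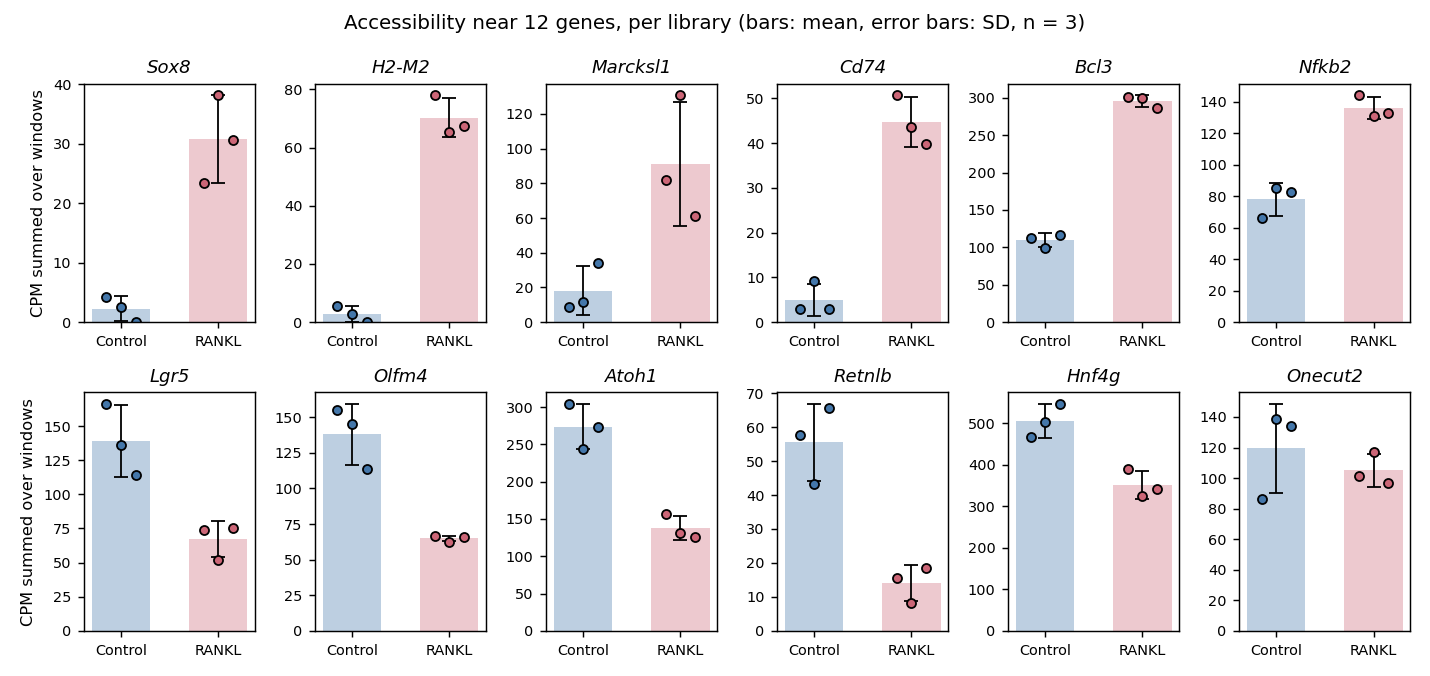
Accessibility near 12 genes in CPM (y axis, summed over the windows of the gene, each panel with its own scale from 0) in control and RANKL libraries; points are libraries, bars the mean and error bars the SD (n = 3). H2-M2, Sox8 and Cd74 rise from near 0, Lgr5, Olfm4 and Atoh1 fall to a lower level, and the libraries of the groups overlap at Onecut2.

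The list of NF-kB genes, the signalling route downstream of RANK, was called higher as well. Of 28 tested members 12 rose, 1 fell and 15 were not called with adjustment over all genes. The list had a camera adjusted p of 6.682e-05, and of 0.1391 with an estimated correlation (0.0163). Adjusted over the list alone, 13 were higher and 1 lower. Bcl3, an atypical IkB protein that acts in the nucleus (chromosome 7, 19808462 to 19822824), had the smallest p of all genes: all 4 of its windows were higher, and their sum rose from 109.7 ± 9.1 to 295.6 ± 8.0 CPM (SD, n = 3 per group), a log2 fold change of 1.44 ± 0.15 (SE) with an edgeR adjusted p of 3.83e-18. Its most responsive window, at 19832141 to 19832340 and 9416 bp outside the gene, had a log2 fold change of 2.63. Birc3, which encodes a cellular inhibitor of apoptosis, rose by 0.99 ± 0.19, Traf2, an adaptor of TNF receptors, by 0.83 ± 0.19 and Nfkb2, the precursor of the p52 subunit, by 0.80 ± 0.20 (log2 fold change, SE). From windows within 5 kb of a gene end alone the calls ended for Bcl3 (0.73, adjusted p = 0.05206) and Traf2 (0.38, 0.2712), and within 1 kb for Traf2 (0.35, 0.3175). Relb, which encodes the partner of p52, had a log2 fold change of 0.21 ± 0.14 (edgeR adjusted p = 0.3543). Of the 3 windows of Relb tested alone, 1 was called higher, at 3659 bp inside a gene end (1.06, edgeR adjusted p = 0.04807). Rel was the member that fell, by 0.61 on the log2 scale (chosen after its value was seen).

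The list of MHC and antigen processing genes was called higher. Of 16 tested members 5 rose, 1 fell and 10 were not called with adjustment over all genes. The list had a camera adjusted p of 0.005059, and of 0.2183 with an estimated correlation (0.016). Adjusted over the list alone, 7 were higher and 1 lower. Cd74, the invariant chain of MHC class II, rose by 2.96 ± 0.56, the class II gene H2-Eb1 by 1.49 ± 0.39, the peptide transporter gene Tap2 by 1.21 ± 0.34 and the class I gene H2-K1 by 1.13 ± 0.25 (log2 fold change, SE). Cd74 and H2-K1 had a single window each, that of Cd74 with 2.82 to 9.15 CPM in the controls. Ctsh, which encodes a lysosomal protease, was the member that fell (chosen after its value was seen). Markers of haematopoietic cells, which also carry class II genes, had 1 of 8 tested members higher, Zap70, whose call ended without RANKL replicate 2 (adjusted p = 0.0648) and after thinning (0.06289), and the list was not called (camera adjusted p = 0.615). With all libraries thinned to the same depth the antigen presentation list was not called (adjusted p = 0.2194, 12 of 16 genes left to test). In another random thinning the median log2 fold change of 12 genes was 0.488 before and 0.637 after.

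The list of crypt stem cell markers and Wnt targets was called lower, with most members not called. Of 24 tested members none rose, 6 fell and 18 were not called with adjustment over all genes. The list had a camera adjusted p of 0.005977, and of 0.2974 with an estimated correlation (0.0338). Adjusted over the list alone, 7 were lower. Lgr5, the R-spondin receptor gene that marks crypt base columnar stem cells (chromosome 10, 115450314 to 115587780), went from 138.8 ± 26.3 to 67.0 ± 13.2 CPM (SD, n = 3 per group), a log2 fold change of -1.06 ± 0.21 (SE) with an edgeR adjusted p of 1.385e-05. The organoid line carries a reporter at Lgr5 in both groups. Olfm4, another stem cell marker, had a log2 fold change of -1.12 ± 0.21, Sox9, a transcription factor of crypt progenitors, of -0.72 ± 0.15 and Cd44 of -0.47 ± 0.14 (SE). The list was not called from windows within 5 kb of a gene end (adjusted p = 0.3569) or within 1 kb (adjusted p = 0.5091), where Sox9 had -0.06 (adjusted p = 0.8996) and -0.08 (0.8632). The Cd44 call ended without control replicate 1 (adjusted p = 0.09447), without RANKL replicate 3 (0.05812), with DESeq2 (0.06597) and within 5 kb (0.06256). The Olfm4 call ended with windows within 200 kb (-0.31, 0.1699).

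**Figure D2:**
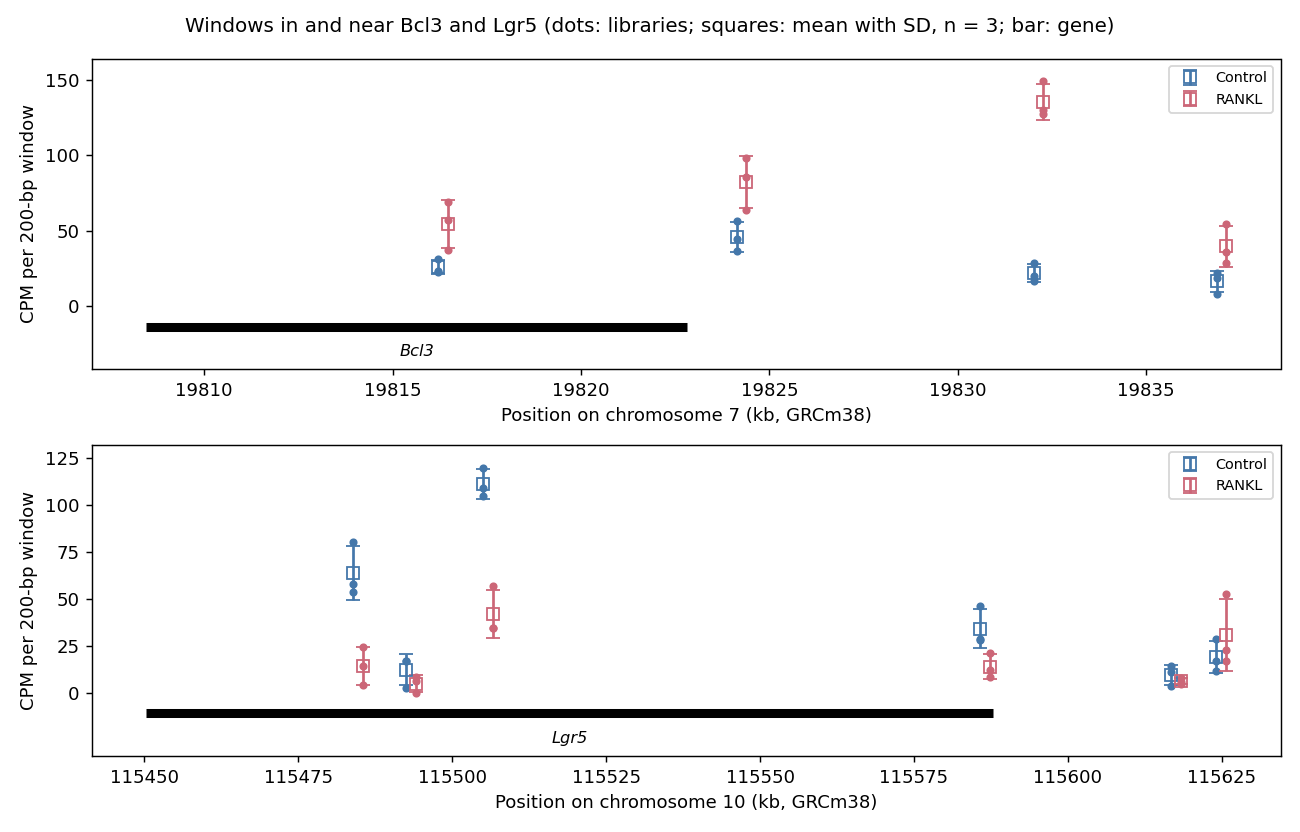
Accessibility in CPM per 200-bp window (y axis) against position in kb on chromosome 7 around Bcl3 (top) and on chromosome 10 around Lgr5 (bottom); dots are libraries, squares with bars the mean and SD (n = 3 per group), and the black bar the gene. All 4 windows at Bcl3 are higher with RANKL, and the 3 strongest control windows inside Lgr5 are lower, of which that at 115505836 lies over 50 kb from a gene end and is not in the sum for Lgr5.

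The list of goblet cell markers was called lower. Of 19 tested members none rose, 6 fell and 13 were not called with adjustment over all genes. The list had a camera adjusted p of 0.005627, and of 0.3482 with an estimated correlation (0.0868). Adjusted over the list alone, 9 were lower and 1 higher. Atoh1, the transcription factor that specifies secretory cells, had a log2 fold change of -1.03 ± 0.15, Retnlb of -1.86 ± 0.40, Bcas1 of -0.71 ± 0.13 and Spink4 of -0.65 ± 0.19 (SE). The list call was lost from windows within 5 kb of a gene end (adjusted p = 0.08158) and after thinning to the same depth (adjusted p = 0.06281). The Spink4 call ended without control replicate 1 (adjusted p = 0.05885), without RANKL replicate 3 (0.05347) and with DESeq2 (0.05046). The Bcas1 call ended within 5 kb (0.2002) and 1 kb (0.7923).

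The ONECUT and HNF4 genes did not move alike. Onecut2 (chromosome 18, 64340032 to 64398488) had 119.5 ± 29.1 CPM in control and 105.1 ± 10.9 CPM in RANKL libraries (SD, n = 3 per group), a log2 fold change of -0.18 ± 0.19 (SE) with an edgeR adjusted p of 0.5855, so that no change was called. Of 100 simulated genes changed 2-fold 63 were called, but these were drawn from genes of all depths and do not give the chance for Onecut2 itself. Its estimate and SE lie far from a 2-fold change in either direction, while a smaller change can be missed. Onecut1 rose by a log2 fold change of 0.90 ± 0.19 (SE, edgeR adjusted p = 0.000111), which came from a window 19746 bp outside the gene at chromosome 9, 74909295 to 74909494, with a log2 fold change of 2.27, and its windows within 5 kb of a gene end had the opposite sign without passing the test. Hnf4g, a transcription factor of enterocytes, had a log2 fold change of -0.53 ± 0.11 (SE, edgeR adjusted p = 5.655e-05) over 9 windows, of which 2 were called lower and 0 higher. Hnf4a had 0.05 ± 0.11 (adjusted p = 0.7934). Of the 7 windows of Hnf4a tested alone, 1 was called higher, at 1673 bp outside the gene (0.98, adjusted p = 0.0072). The list of intestinal transcription factors had 2 members higher and 8 lower of 36 tested and was not called (camera adjusted p = 0.2305).

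Enterocyte markers were not called as a list, with 1 higher, 4 lower and 26 passing no test of 31 (camera adjusted p = 0.5226). The brush border enzyme genes Sis and Mep1a had log2 fold changes of -0.70 ± 0.13 and -1.05 ± 0.23, and Cyp3a11 of -0.84 ± 0.24, while Dgat1, which encodes an enzyme of triglyceride synthesis, rose by 0.96 ± 0.26 (SE), a call that ended without control replicate 2 (adjusted p = 0.06112) or RANKL replicate 3 (0.05315). The Cyp3a11 call ended with DESeq2 (adjusted p = 0.05168) and after thinning (0.2641). The Sis call ended from windows within 5 kb (-0.66, 0.1266) and within 1 kb (-0.81, 0.08403). The single window at Alpi, 30 bp outside the gene, was below the filter, with 7, 13 and 3 counts in the controls and 6, 5 and 17 with RANKL. Genes of the villus tip (2 higher and 3 lower of 16, camera adjusted p = 0.9257), of the villus bottom (none higher and 2 lower of 13, 0.9257) and of fatty acid oxidation and PPAR targets (1 higher and 1 lower of 21, 0.3644) were not called.

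Other epithelial lists were mixed. Of 18 tuft cell genes 2 were higher and 3 lower (camera adjusted p = 0.9257), with Rgs13 at -1.09 ± 0.23 and Sucnr1, the succinate receptor gene, at -1.01 ± 0.25. Of 9 Paneth cell genes 1 was higher, Guca2b at 2.14 ± 0.44, and 1 lower, Mptx1 at -1.06 ± 0.30 (log2 fold change, SE, camera adjusted p = 0.6854). Of 14 enteroendocrine genes 1 was higher, the hormone gene Gip (camera adjusted p = 0.9257), a call that ended in 8 alternative settings, among them leaving out control replicate 2 (adjusted p = 0.0631), control replicate 3 (0.1147), RANKL replicate 1 (0.05331) or RANKL replicate 2 (0.2522). Genes of fetal-like or regenerating epithelium had 4 higher and 1 lower of 20 (camera adjusted p = 0.5226), with Ankrd1 at 2.86 ± 0.52, Msln, which is also in the M cell list, at 2.85 ± 0.49, and Sprr1a at 1.68 ± 0.38; their median was -0.01 while their mean was 0.36, and with windows within 200 kb Ankrd1 had 0.40 (adjusted p = 0.3222). Cell cycle genes had 3 higher and 1 lower of 24 (camera adjusted p = 0.6854), with Stmn1 at 1.36 ± 0.26 and Rrm2 at -0.71 ± 0.16, and endocytic and lysosomal genes 2 higher and 1 lower of 26 (0.6854), with Ctsd at 1.26 ± 0.27 and Lamp2 at -0.80 ± 0.22 (log2 fold change, SE). The Lamp2 call ended without RANKL replicate 2 (adjusted p = 0.05825). From windows within 1 kb of a gene end the calls of Stmn1, Rrm2, Ctsd and Lamp2 ended (0.3519, 0.5398, 0.0826 and 0.4941). Those of Rrm2, Ctsd and Lamp2 ended within 5 kb too (0.5602, 0.06662 and 0.3257), and that of Ctsd in 2-kb windows (0.07772).

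Lists for other cell types were not called: endothelial cells (3 higher and 1 lower of 10, camera adjusted p = 0.9257), mesenchymal cells (1 higher of 10, 0.9257) and enteric neurons and glia (1 lower of 6, 0.9257). Signs differed between the median, the mean and the test for endothelial genes (median -0.16, mean 0.10, test downward), neural genes (0.05, 0.07, downward), villus bottom genes (0.05, -0.03, downward), villus tip genes (0.03, 0.01, downward) and tuft cell genes (0.00, -0.08, downward). Of 17 housekeeping genes 1 was higher, Gapdh, at 0.73 ± 0.26 (SE) with an edgeR adjusted p of 0.03351 from a single window, and the list was not called (camera adjusted p = 0.3666). The Gapdh call ended in 9 alternative settings, among them leaving out control replicate 2 (adjusted p = 0.135), control replicate 3 (0.07122) or any of RANKL replicates 1, 2 and 3 (0.07086, 0.05915 and 0.1088).

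**Figure D3:**
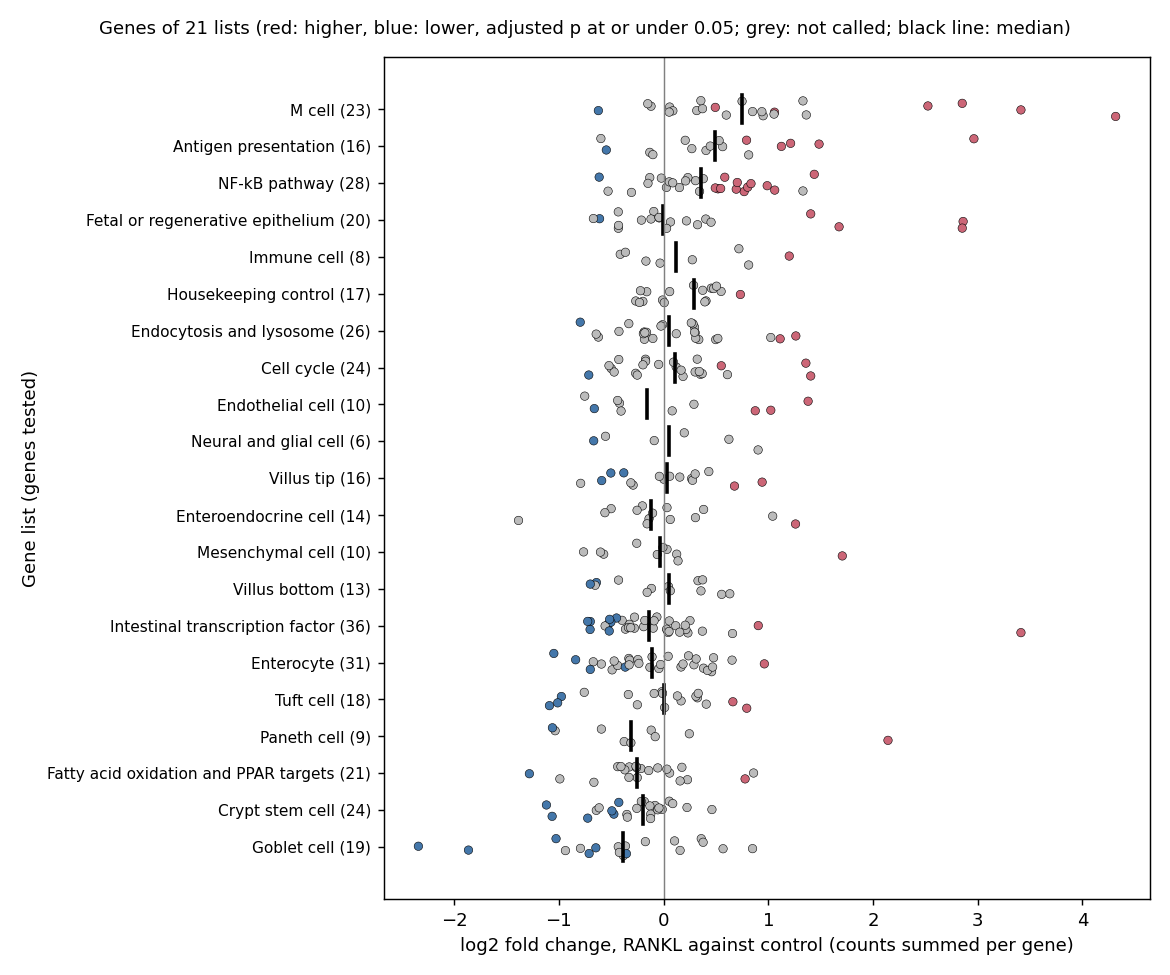
Log2 fold change of RANKL against control (x axis) for the tested genes of 21 lists (y axis, number of genes tested in brackets); each point is a gene, red where higher and blue where lower at an adjusted p of 0.05, grey otherwise, and the black line is the median of the list. M cell, antigen presentation and NF-kB lists lie furthest to the right, with medians of 0.75, 0.49 and 0.36, and the goblet cell list has a median of -0.38.

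The genes with the largest rises among well covered genes with at least 2 windows, tested alone or not, were Neurl1a (log2 fold change 1.76 ± 0.20, SE), Zmym4, Extl1, Cd200r2, Mmp20, Bcl3, Arpp21, Plb1, Klhl5 and Rngtt (1.36 ± 0.22). The largest falls reported here were at Olfr948 (-2.34 ± 0.29), Tent4a, Ambn, Rassf9, Zfp957, Rbm38, Tmem182, Lor and Pla2g4a (-1.69 ± 0.22). Klhl5, Olfr948, Ambn, Zfp957 and Lor each had 1 window deep enough to test alone. Zmym4, Cd200r2, Arpp21 and Plb1 each had 1 called window. The called windows of Cd200r2, Olfr948 and Ambn are those given above among the largest window changes. The rise of Zmym4, 1.68, depended on the assignment of windows: it was 0.36 (adjusted p = 0.5745) from windows within 5 kb and 0.15 (0.7154) with the nearest gene body. Zfp957 had -1.34 (adjusted p = 0.05206) from windows within 5 kb. At Tent4a, which encodes a non-canonical poly(A) polymerase, and at Pla2g4a, which encodes cytosolic phospholipase A2, 3 windows each were lower and none higher.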

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

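The tests on background reads in windows higher and lower with RANKL and on library depth were chosen only after the results were seen, as were the 2-kb counts. The loess test of lower windows replaced an earlier test, the share of higher calls among the strongest windows (47.6%), which the scaling itself centres, and the depth test over all list members replaced that over members past the filter. In the 2-kb counts, used above only as an alternative, 2862 windows were higher with RANKL that were too shallow to test in 200 bp, against 621 lower ones (edgeR adjusted p at or under 0.05). These values lie outside the main measurement. Among the stronger windows tested in both counts the 2-kb calls leaned the other way, 1319 higher and 4455 lower, and loess offsets changed all 2-kb calls from 4181 higher and 5076 lower to 3866 and 3065. A trend with abundance stays open as the cause of this split, which is not read as a gain of accessibility.

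The first pattern is the set of windows called higher or lower, for which more background reads in the RANKL libraries, where the central 200 bp held a smaller share of the 2-kb reads, is a candidate technical explanation. Windows called higher from 2 replicate pairs had, in the pair left out, a larger central share with RANKL than in control, by 4.774, 3.627 and 2.593 percentage points with 95% exact binomial intervals that did not overlap, where background would lower it; a first bound of 3 points for replicate 3 was not met. The share was lower with RANKL in windows called lower (-6.931, -9.884 and -8.656 points), as both a lost peak and background give, and in uncalled windows (-1.381, -3.288 and -2.869), as background gives. Among the weakest 25% of windows 864 were higher and 395 lower, a skew that background would give, and loess offsets, which remove any trend with abundance, left 646 and 548 there and kept 88.2% of all higher and 96.0% of all lower calls, although here they raised the number of lower calls to 2313 and so could hardly end them, while in 2-kb counts they cut 4181 higher and 5076 lower calls to 3866 and 3065. These values argue against background as the whole cause of the higher windows and leave open a part of it, above all among weak ones; for the lower windows background stays open, as do differences in cell composition with RANKL.

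The second pattern is that higher windows were less often distal than lower ones in 200-bp counts (odds ratio 0.329) and more often in 2-kb counts (odds ratio 4.13). Windows tested in 2-kb counts alone were not the cause, since the odds ratio was 2.611 (95% interval 2.24 to 3.06) over the 21617 windows tested in both. More background in the RANKL libraries would lower the share of flank reads near gene ends, and that share was 41.3%, 39.4% and 40.8% in RANKL replicates 1, 2 and 3 against 44.5%, 45.7% and 46.3% in the controls, a difference of -4.988 points. With loess offsets against abundance the odds ratio of the 2-kb counts was 0.716, on the side of the 200-bp counts. Background would give the flank values. In central reads the share near gene ends was 46.0%, 44.1% and 44.0% in RANKL replicates 1, 2 and 3. It was 41.4%, 43.2% and 44.3% in the controls, so the groups overlapped there. In 200-bp counts the odds ratio stayed under 1 with loess offsets (0.311) and in windows at or above the median strength (0.142). A true spread of accessibility around distal windows with RANKL was not tested, so the place of the changed windows stays open.

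The third pattern is the rise of the M cell and NF-kB lists and the fall of the crypt stem cell and goblet lists. Against 10000 random lists matched on mean accessibility, the median change lay at percentile 100 for the M cell and for the NF-kB list and 0.1 for the goblet list. This argues against the strength of their windows as the cause. The antigen presentation list, also called, lay at 99.77. The housekeeping list lay at 98.42 and the fatty acid oxidation and PPAR list at 2. Neither was called by camera, so this test does not single out called lists. The crypt stem cell list lay at percentile 9.64, inside the central 95% of random lists, so for this list the strength of its windows cannot be told apart from a change of its own. Thinned to the same depth, the medians over all tested members kept their sign and at least 0.815 of their size. Thinning keeps the expected ratios between libraries, so these medians could hardly change and cannot decide about depth, which stays open. For the 14 of 23 M cell genes still past the filter the median was 0.34 before and 0.24 after, against 0.75 for all. For 13 of 19 goblet genes it was -0.355 before and -0.240 after. An effect of RANKL, or of the treatment before it, on the share of M, stem and goblet cells remains a hypothesis. It comes from the same data as the list calls, and cell shares were not measured. Lists called at a preset correlation were not called at an estimated correlation. For the M cell list this held although its estimate, 0.00196, was below the preset 0.01, so the size of the correlation does not account for that loss. With fry, which asks whether a list's own genes move in a single direction, the same lists were called. The fry adjusted p was 0.006008 for the M cell and for the NF-kB list and 0.02144 for antigen presentation. It was 0.03747 for the crypt stem cell and 0.03362 for the goblet list.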

How the results depend on the processing

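The 2-kb counts, the deposited scores, thinning, windows held mainly by a single library and the nearest gene body were chosen after seeing the data. Over 115 named genes and windows, 1840 of 2028 alternative values kept their direction and side of the threshold, 151 lost and 24 gained a call and 13 changed sign. Settings in which a named gene or window was not tested, for example below the filter, gave no value. They are not among the 2028 and do not count as lost calls, so these numbers can overstate how far calls held. Windows numbered 2166 higher and 2169 lower. They were 3204 and 1973 without a filter on low counts, which kept 75.4% of the lower calls, 831 and 963 with at least 20 counts in every library of a group, 1264 and 1039 with DESeq2, 1344 and 1253 at an adjusted p of 0.01, 915 and 767 against a fold of 1.5, 478 and 712 after thinning and 4181 and 5076 in 2-kb windows (3866 and 3065 there with loess offsets, also chosen after seeing the data); without each library in turn they were 1337 to 2802 and 1475 to 2229, the lowest without RANKL replicate 3. Thinning and the stricter filter leave fewer counts to test and 2-kb windows more; the cause of the other differences was not tested. With the replicate block they were 1807 and 1827, genes 704 and 890 and lists 3 and 2, with 1757 and 1775 windows and 677 and 859 genes called both with and without it. Among named genes, windows and lists the block ended the calls of Epn2, Flt1, Sh2d6, Ccl25 and Junb, added Ppargc1a and Reg3g and changed no other call. Genes, 869 higher and 1052 lower, were 408 and 487 with DESeq2, 385 and 498 from windows within 5 kb, 219 and 300 within 1 kb, 378 and 504 after thinning, 1466 and 1920 in 2-kb windows, and 545 to 848 and 672 to 933 without each library (567 and 672 without control replicate 1, 545 and 678 without RANKL replicate 3). The distal share of higher windows reversed in 2-kb windows (88.9%), though not there with loess offsets (72.0%, against 78.2% of lower windows). It was 61.8% to 73.4% without each library, below the share of lower windows each time. Called lists, 3 higher and 2 lower, were 0 and 0 with an estimated correlation, 2 and 1 after thinning, 3 and 0 from windows within 5 kb and 3 and 1 within 1 kb, and the lower ones were 3 with fry, which added the intestinal transcription factors; without each library they were 3 and 2 throughout. Changes of sign, of unknown cause where not due to dropping distant windows, were at Ccl20 (-0.06 without control replicate 2, -0.14 without RANKL replicate 2, and up to 0.18 without RANKL replicate 1, -1.06 within 5 kb, -1.09 within 1 kb, -0.19 in 2-kb windows), Mcm5 (-0.21 within 5 kb, -0.20 within 1 kb), Onecut1 (-0.57 and -0.59), Apobec1 (0.014 within 5 kb), Cd44 (0.062 within 1 kb), Cd2 (0.45) and Des (0.050) in 2-kb windows. Under TMM factors, DESeq2 size factors and total counts the median window and the median gene stayed within 0.1 of 0 on the log2 scale. The motif tests and GC corrections, with or without the block, were not run. Depth limits all of this: 39.3% of windows could be tested.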

Other observations

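The genes in the first paragraph and the window near Spib were chosen after their values were seen, and the tests of other splits were planned. Some genes changed at many windows in the same direction: 18 genes had at least 3 lower and no higher windows and 8 had at least 3 higher and no lower ones. The higher set included Bcl3, Il23r, which encodes a subunit of the interleukin 23 receptor (log2 fold change 1.32 ± 0.20, SE), Mmp20 and Map3k13, which encodes a kinase of the JNK route (0.59 ± 0.16). The lower set included Pla2g4a, Kif12 (-1.52 ± 0.20), Acss1, the mitochondrial acetyl-CoA synthetase gene (-1.47 ± 0.19), Galnt4, which encodes an enzyme of mucin-type O-glycosylation (-1.04 ± 0.17), Ctsc, which encodes a lysosomal protease (-0.84 ± 0.14), and Nnt, which encodes the mitochondrial transhydrogenase (-0.88 ± 0.16; edgeR, n = 3 per group). Genes with more windows have more chances to enter either set.

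Next to Spib, whose own window was too shallow to test, a window at chromosome 7, 44525246 to 44525445, 630 bp from Mybpc2, rose by a log2 fold change of 1.21 ± 0.25 (SE) with an edgeR adjusted p of 4.174e-05.

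Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 4335 called windows, 1921 called genes and 5 called lists; the highest of the others gave 0, 0 and 1. As many calls came from 1 of the 10 splits in each case. The 3 other splits that part all replicate pairs gave at most 0 windows, 0 genes and 1 list. With 10 splits no share under 0.05 can be reached.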
